A study of Mus musculus with 2 samples.

How the data were processed

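Single-cell RNA-seq of the mouse small intestine was used to compare cells after ischemia-reperfusion injury (IRI) with cells after sham surgery. Per the labels' protocols, the superior mesenteric artery of C57BL/6 mice was clamped for 45 min and released, and lamina propria cells were collected 6 h later. Sham mice had the same surgery without the clamp. Cells were released enzymatically, taken from the layers between 30% and 70% Percoll, depleted of dead cells and of CD11b-positive cells with magnetic beads, and fixed for 19 h at 4 °C. Cells of 3 mice were pooled in each group, which left 1 library per group. Fixed cells were hybridised with pairs of gene-specific probes, each group with its own probe barcode, and the groups were mixed before droplet encapsulation.

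The deposited values are UMI counts per gene and cell, that is, ligated probe pairs counted as molecules and not normalized by the authors. Cell Ranger 7.1.0 and the genome build mm10 are named in the submitters' processing notes. How barcodes were called as cells is not given in the sources used here. A probe panel measures only genes that have probes, so 19059 genes were read, and 37 immunoglobulin genes and Jchain covered only part of the antibody repertoire. Near-identical families, among them the metallothioneins, Reg3 genes, alpha-defensins, mast cell proteases and immunoglobulin kappa variable genes, can share probe signal and are uncertain at the level of the single gene. Data of purified CD4+ cells that the submitters placed in another series were not used here.

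Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept. Doublets were called per library with Scrublet (scanpy 1.11.5, expected rate 6%, 30 principal components) and removed, 554 in the sham and 418 in the IRI library. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes chosen per library gave 50 principal components. Clusters were found with the Leiden method (igraph 0.11.9, resolution 1) on a shared-neighbour graph of 15 neighbours, on both libraries together and without integration. Clusters were named from fixed markers and are called X-like. A name needed at least 3 detected markers, at least 20 cells, and no more markers of another class than of its own among the 10 genes of highest fold. The constants of the naming score were set after the clusters were seen. Of 36 clusters, 32 were named and 4 stayed unnamed. Cells taken as CD4 T cells came from T-like clusters and had at least 1 Cd4 UMI and no Cd8a or Cd8b1 UMI.

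Raw UMIs were summed over the cells of a class in each library and scaled to a common total (CPM). The ratio of IRI to sham CPM is given on the log2 scale with an exact conditional-binomial 95% interval. Shares of cells have exact Clopper-Pearson 95% intervals and CPM have exact Poisson 95% intervals. All these intervals cover counting error only. With 1 library per group there is no replicate check, no test was made between conditions, and no p-value or count of significant genes is given. A gene with no UMI in one library was set to 3 counts there, and its ratio is a bound under that setting. It is not the lower limit of the 95% interval, which was smaller. For Clca4b in the whole library that limit was 5.29, against a log2 ratio of 5.61. Classes with at least 50 cells in each library were compared, and the 9 with at least 200 cells in each were the main comparisons.

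For each main comparison the rule for named genes took the 10 largest and the 10 smallest CPM ratios among genes with at least 100 UMIs over both libraries and a difference of at least 2-fold. Within a class, the class's own markers were left out, and the gene's CPM in the library where it was higher had to reach 0.2 of the highest CPM of any compared class. In the smaller classes and in the innate lymphoid classes, 5 genes per direction are printed, or fewer where the text says so. For each gene list described, the up to 4 members with the largest absolute log2 ratio are given. Some genes that these rules took are not reported here. The 26 gene lists were summarised by the median log2 ratio of members with at least 20 UMIs. The percentile of that median among 10000 random lists of the same size, matched on mean expression in 10 bins, describes these 2 libraries and is not a test. The gene lists, markers, comparisons and thresholds, other than the constants of the naming score, were chosen before the data were examined. Of 508 list genes, 495 were measured.

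The ratio and percentile calculations were tested on simulated Poisson counts drawn from the real means and library sizes, with 200 genes changed. The intervals assume such counts, so coverage near 95% checks the calculation only. The uneven spread of UMIs over cells was not simulated. For the T-like class (11419 genes), the interval covered the true value for 95.3% of unchanged genes. The true value was covered for 94.0% of genes changed by 2-fold and 99.0% of genes changed by 4-fold, and every changed gene had the right direction in each simulation. For fibroblasts (11873 genes), coverage was 95.7% for unchanged genes, 94.0% at 2-fold and 91.0% at 4-fold. For the whole library (15090 genes) it was 95.1%, 93.0% and 94.0%, and for gated CD4 T cells (10046 genes) 95.3%, 91.0% and 95.0%. A cutoff of 2-fold finds only part of genes that differ by 2-fold: 45.0% in the whole library, 58.0% in T-like cells, 46.0% in fibroblasts and 51.0% in gated CD4 T cells.

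Alternatives were other cell filters, other doublet rules, other Leiden resolutions, separate clustering of the libraries, TMM factors from edgeR 4.0.16 in R 4.3.3, median-of-ratios factors, means over cells in place of sums, and other minima of UMIs. In B cell-like, T-like, plasma cell-like and fibroblast-like cells and in gated CD4 T cells, IRI cells were also weighted so that the clusters of a class took their sham shares. Clusters were found from the same genes, so this can remove part of a response. The weighting was not made in ILC2-like, ILC3-like and blood endothelial-like cells. In those classes a different mix of cells and a change within cells were not told apart. Cells were also thinned to 1000 or 2000 UMIs for shares of cells with a UMI. Gene positions are those of the GENCODE M21 annotation, matched by gene identifier, on mm10. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.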

Results

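Gene expression was measured in live CD11b-negative lamina propria cells of the mouse small intestine 6 h after reperfusion (IRI) or sham surgery, with 1 library of 3 pooled mice in each group. The study's title concerns memory-phenotype CD4 T cells in ischemic organs, and these libraries profile the surrounding tissue. The sham library held 11211 cell barcodes and 144841022 UMIs, with a median of 5809 UMIs per cell. The IRI library held 10378 barcodes and 118349331 UMIs, with a median of 6206 UMIs per cell. After filters and doublet removal, 10601 sham and 9897 IRI cells remained. There were no replicates, so every difference is between 2 pools of mice and all intervals are for counting error alone.

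T-like, ILC2-like and fibroblast-like cells took larger shares of the IRI library, and plasma cell-like, B cell-like and blood endothelial-like cells took smaller ones. T-like cells made up 13.8% of sham cells (95% interval 13.1 to 14.5) and 18.7% of IRI cells (18.0 to 19.5). ILC2-like cells, innate lymphocytes that make type 2 cytokines, made up 10.4% (9.80 to 10.97) and 14.1% (13.4 to 14.8). Fibroblast-like cells made up 4.07% (3.70 to 4.46) and 5.96% (5.50 to 6.45). Plasma cell-like cells, which secrete antibody, made up 18.8% (18.0 to 19.5) of sham and 12.2% (11.5 to 12.8) of IRI cells.

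B cell-like cells made up 26.3% (25.5 to 27.2) of sham and 23.3% (22.4 to 24.1) of IRI cells. Blood endothelial-like cells made up 3.38% (3.04 to 3.74) and 2.30% (2.02 to 2.62). For ILC3-like cells, innate lymphocytes of the mucosa, the shares were 12.3% (11.7 to 13.0) and 12.0% (11.4 to 12.7), and for NK or ILC1-like cells 3.45% (3.11 to 3.82) and 3.77% (3.40 to 4.16). Epithelial-like cells made up 3.69% (3.34 to 4.07) and 3.04% (2.71 to 3.40). Mast or basophil-like cells numbered 5 in the sham and 28 in the IRI library. The bead depletion of CD11b-positive cells, the Percoll layers and the dead cell removal acted on these shares, so they are shares of the sorted suspension and not of the tissue. Median UMIs per cell also differed within classes, for example 8540 in sham and 12003 in IRI fibroblast-like cells. The B cell-like ratio of IRI to sham share, 0.884, was 0.501 under a stricter cell filter, where 1 B-like cluster of 1647 sham and 1760 IRI cells stayed unnamed.

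**Figure D1:**
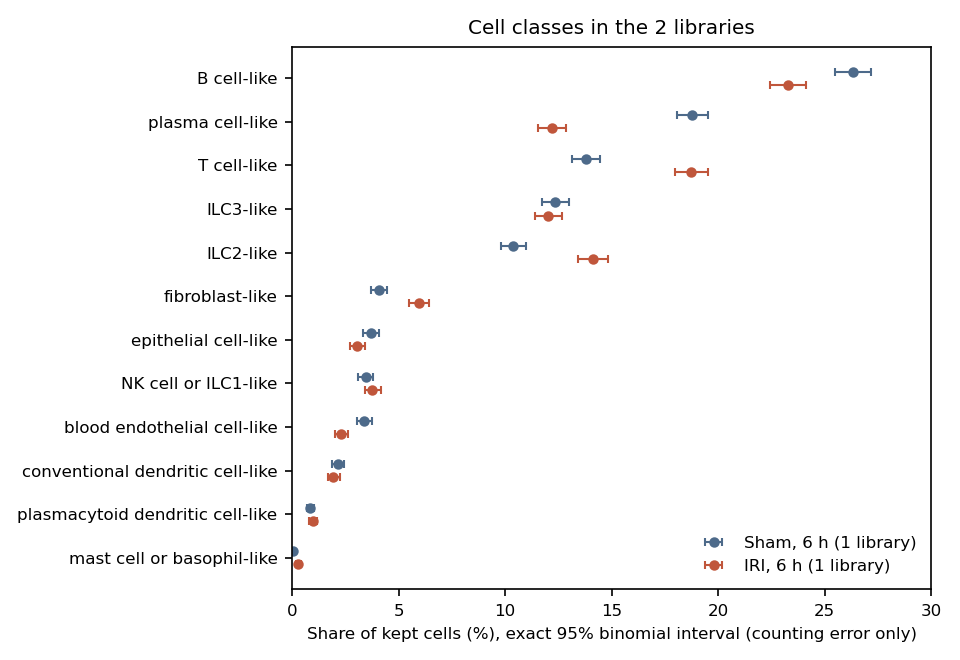
Share of kept cells (x axis, percent) of each cell class (y axis) in the sham and the IRI library; points are the shares and bars are exact 95% binomial intervals, counting error only. T-like cells lie at 13.8% in sham and 18.7% in IRI, and plasma cell-like cells at 18.8% and 12.2%.

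Over the whole library, genes of matrix remodelling, chemokines, cytokines, metallothioneins and glucocorticoid-inducible genes were higher after IRI, and MHC class II genes were lower. Antibody light chain genes differed in both directions. Immunoglobulin transcripts took 45.3% of sham and 31.7% of IRI UMIs, and the median log2 ratio of all 15090 measured genes was 0.34. Values are therefore set beside that shift, or beside the same ratio with the sham class shares given to both libraries. For the gene lists and their members, Cxcl5 apart, only the shift is given. A different mix of classes can be part of those values. Fibroblast-like cells, for example, held 4023156 of 131147555 sham UMIs and 7394167 of 109481766 IRI UMIs. Cxcl5, a chemokine that attracts neutrophils, had 11.4 CPM in sham and 421 CPM in IRI, a log2 ratio of 5.21 (95% interval 5.14 to 5.28), or 4.41 with sham class shares. Calca, the precursor of calcitonin gene-related peptide and one of the markers used to name ILC2, had 3.54 and 148 CPM, a log2 ratio of 5.39 (5.25 to 5.52), or 4.73 with sham class shares.

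Further genes with the largest ratios were Ptx3, a secreted pattern recognition protein (log2 ratio 5.01, and 4.21 with sham class shares), Kcne4, a potassium channel subunit (4.68 and 3.89), Clec4e, a receptor for dead cells and microbes (4.64 and 4.31), and the metallothionein Mt4 (7.30 and 6.52), which shares sequence with Mt1 and Mt2. For Clec4e, with 8 sham UMIs, 3 cells held 44.6% of the IRI UMIs. The ratios of 4 other genes rested on fewer cells. The share of their IRI UMIs in the 3 cells with most was 95.5% for Cps1, 83.7% for F13a1 and 72.1% for Tac1, and Clca4b UMIs were found in 4 cells only. Cps1, a urea cycle enzyme, had a log2 ratio of 6.26, the clotting factor subunit F13a1 6.20, and Tac1, the substance P precursor, 5.57, or 4.41 with sham class shares. For Clca4b the sham library had 0 UMIs, and it was at least 48.7-fold higher.

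Among the lowest ratios were the light chain genes Igkv5-45 (-5.89, and -5.53 with sham class shares), Igkv6-25 (-3.21 and -2.84), Igkv2-137 (-3.21 and -2.84), Igkv8-30 (-3.16 and -2.78) and Igkv13-84 (-2.81 and -2.43). Of the Igkv5-45 UMIs in sham, 73.3% lay in 3 cells. The others were Apol7c (-3.97), the lactate receptor gene Hcar1 (-3.35), Zfp683, a transcription factor of tissue-resident lymphocytes (-2.90), Syt15 (-2.72) and Nmbr, a neuropeptide receptor gene (-2.54). Of the Apol7c UMIs in sham, 56.3% lay in 3 cells.

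Matrix remodelling and wound response genes had a median log2 ratio of 1.53, at percentile 100 of random lists whose median was 0.34. Of 21 measured, 11 were at least 2-fold higher and 1 at least 2-fold lower. Tnc, a matrix glycoprotein of wounds, had a log2 ratio of 4.29 (4.14 to 4.45), the matrix proteases Mmp10 2.80 (62.75% of its IRI UMIs in 3 cells) and Mmp3 2.74, and the IL-33 receptor gene Il1rl1, also an ILC2 marker, 2.65. Chemokine ligands had a median of 1.0035 (percentile 100), and 16 of 32 were at least 2-fold higher and 2 at least 2-fold lower. Besides Cxcl5, the monocyte attractants Ccl7 (4.01) and Ccl2 (3.28) and the neutrophil attractant Cxcl1 (3.05) differed most. Innate cytokines and alarmins had a median of 0.79 (percentile 100), with 10 of 25 at least 2-fold higher, among them Csf3 (2.78), Il25 (2.46, from 5 and 23 UMIs), Il6 (2.39) and Tslp (2.24).

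Glucocorticoid-inducible genes had a median of 0.84 (percentile 100), and all 11 were higher, with Map3k6 at 1.80, Fkbp5, a co-chaperone of the glucocorticoid receptor, at 1.44, Ddit4 with 154 and 309 CPM and Pik3ip1 with 25.9 and 51.6 CPM. Oxidative stress and metallothionein genes had a median of 0.77 (percentile 100), with Slc7a11, which imports cystine, at 3.13, Mt1 at 2.62, Mt2 at 2.55 and Hmox1, which degrades heme, at 1.71. Hypoxia-inducible genes stood close to the shift of all genes, with a median of 0.44 against 0.34 (percentile 98.0, or 66.7 with means over cells). Their largest ratios were those of Ndrg1 (1.76), Slc16a3 (1.56), Ldha (1.15) and Pfkfb3 (0.93). Immediate-early genes had a median of 0.20, below that of random lists (percentile 0.46, but 5.76 with means over cells and 3.12 against random lists not matched on expression), and it was -0.14 after scaling with TMM factors. Their largest ratios were Ier3 (0.90), Fosl1 (0.64), Ier5 (0.63) and Myc (0.59). MHC class II genes, which present antigen to CD4 T cells, had a median of -0.21 (percentile 0), with H2-DMb2 at -0.86, Ciita at -0.67, H2-DMb1 at -0.50 and H2-Ab1 at -0.41. B cell markers, at -0.33, moved with them.

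**Figure D2:**
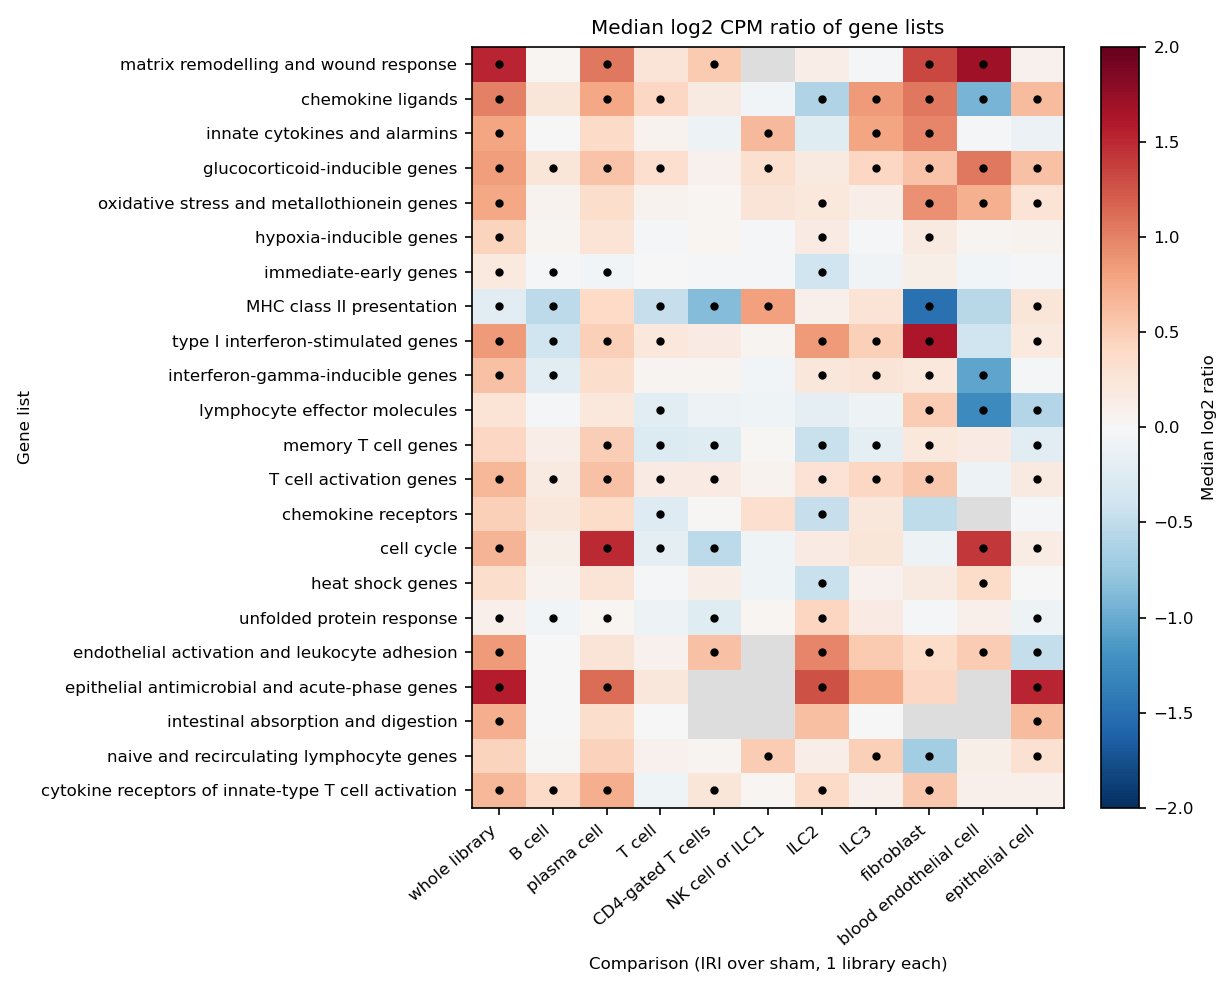
Median log2 ratio of IRI to sham CPM (colour) of each gene list (y axis) in each comparison (x axis), 1 library per group; grey cells had too few measured members, and a dot marks a median in the upper or lower 2.5% of matched random lists. Matrix genes had medians of 1.53 in the whole library, 1.33 in fibroblast-like and 1.70 in blood endothelial-like cells.

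In fibroblast-like cells, neutrophil and monocyte chemokines, cytokines, interferon-stimulated genes and metallothioneins were higher after IRI, and MHC class II genes were lower. The comparison used 431 sham and 590 IRI cells, and the median log2 ratio of all genes was -0.21. Cluster 21, whose top genes began with Cxcl5, Ptx3 and Cxcl1, held 15.1% of sham and 27.3% of IRI cells. Cluster 19 held 41.1% and 19.7%. A different mix of cells and a change within cells were not told apart in this class. Chemokine ligands had a median log2 ratio of 1.05 against -0.12 for random lists (percentile 100), with 11 of 21 at least 2-fold higher. With the clusters of the class held at their sham shares the median was 1.18, so it did not rest on the different shares of these clusters. A different mix within a cluster stays open. Cxcl2 had 35.3 CPM in sham and 1298 CPM in IRI, a log2 ratio of 5.20 (4.96 to 5.45), and Cxcl5 had 370 and 6223 CPM, a log2 ratio of 4.07 (4.00 to 4.15). Cxcl3 had a log2 ratio of 6.78 (5.42 to 8.66), with 72.4% of its IRI UMIs in 3 cells, and Cx3cl1 had 3.82 (1.22 to 9.18), from 1 and 26 UMIs.

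Innate cytokines and alarmins had a median of 0.98 (percentile 100), with 8 of 16 at least 2-fold higher and 2 at least 2-fold lower. Il6 was at 3.36 (3.22 to 3.50), Lif, a cytokine of the same family, at 3.18, and Il1b at -2.63, while Tnfsf15 had 0 sham UMIs and was at least 9.61-fold higher, with 73.6% of its IRI UMIs in 3 cells. The Il1b ratio came from 37 and 11 UMIs, in 18 sham and 5 IRI cells, and 3 cells held 45.95% of its sham UMIs. Matrix genes had a median of 1.33 (percentile 100), with 13 of 20 at least 2-fold higher, among them Tnc (3.17) and Thbs1 (2.21). The Mmp13 ratio of 5.37 came from 1 sham UMI and 2 IRI cells. Type I interferon-stimulated genes had a median of 1.61 (percentile 100), with 19 of 25 at least 2-fold higher, among them the antiviral genes Rsad2 (6.71 and 142 CPM), Oas3 (3.82, from 1 and 26 UMIs), Oasl1 (3.52) and Ifit1 (3.28).

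Oxidative stress and metallothionein genes had a median of 0.91 in fibroblast-like cells (percentile 100), with Slc7a11 at 5.33, Mt1 at 2.17, Mt2 with 9301 and 37140 CPM and Srxn1 at 1.66. MHC class II genes had a median of -1.49 (percentile 0), and 8 of 12 were at least 2-fold lower, among them H2-DMb2 (-2.40), H2-Ab1 (-2.26), H2-DMb1 (-2.02) and H2-Eb1 (-1.99). B cell markers were also lower in these cells, with a median of -0.89. The largest ratios by the rule were those of Mt4 (6.87), Cxcl3, Mt3 (6.13), Slc7a11 and Cxcl2. The smallest were those of the imprinted gene Peg3 (-3.44), the intermediate filament gene Synm (-3.18), the Wnt inhibitor gene Apcdd1 (-2.97), Omd (-2.96) and Selenbp1 (-2.88).

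Chemokine and cytokine transcripts came from few classes, and for several the largest source differed between the libraries. Cxcl5 lay on chromosome 5 (90759360 to 90761624, plus strand), and fibroblast-like cells held 99.5% of its sham and 99.7% of its IRI UMIs. Fibroblast-like cells also held 94.0% and 98.7% of Ccl2, 99.3% and 99.6% of Ccl11, an eosinophil attractant, and 91.9% and 97.4% of the alarmin Il33 (chromosome 19, 29925114 to 29960718, plus strand). Of Il6 (chromosome 5, 30013114 to 30019981, plus strand), ILC2-like cells held 65.9% of sham and 24.1% of IRI UMIs, and fibroblast-like cells 15.8% and 68.4%. The Il6 level in ILC2-like cells was 240 CPM (229 to 251) in sham and 250 CPM (240 to 259) in IRI, and in fibroblast-like cells 105 CPM (95.6 to 116) and 1080 CPM (1056 to 1104).

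Of Cxcl2, ILC3-like cells held 70.7% in sham and 46.3% in IRI, fibroblast-like cells 1.13% and 25.8%, and ILC2-like cells 7.58% and 14.8%. Cxcl1 came to 58.7% and 95.8% from fibroblast-like cells. Of Lif, fibroblast-like cells held 5.47% and 45.9%, and ILC2-like cells 55.2% and 29.4%. Csf3, a growth factor of neutrophils, came to 46.1% and 81.5% from fibroblast-like cells. Il5, a cytokine of eosinophils, came to 90.4% and 95.6% from ILC2-like cells. Gzma, a granule protease of cytotoxic lymphocytes, came to 49.7% and 51.0% from T-like cells, whereas for Gzmb the mast or basophil-like share was 4.46% and 25.3%.

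**Figure D3:**
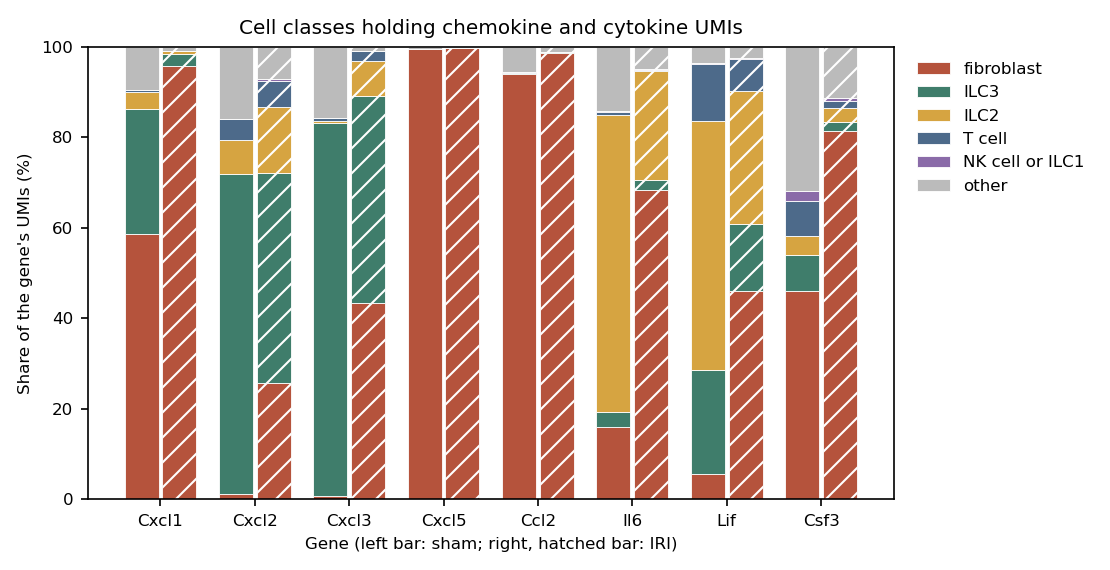
Share of each gene's UMIs (y axis, percent) held by each cell class (colour) for 8 chemokine and cytokine genes (x axis); the left bar of a pair is the sham library and the right, hatched bar the IRI library. For Il6 the fibroblast-like share is 15.8% in sham and 68.4% in IRI.

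In blood endothelial-like cells, metallothioneins, matrix genes and glucocorticoid-inducible genes were higher after IRI, and interferon-gamma-inducible genes were lower. The class had 358 sham and 228 IRI cells, and different clusters held it: cluster 14 held 354 of the sham and cluster 23 held 206 of the IRI cells. The median log2 ratio of all genes was -0.19. Endothelial activation and adhesion genes had a median of 0.50 (percentile 99.98, or 92.3 with doublet calls kept and 84.8 over members with at least 100 UMIs), with 8 of 17 at least 2-fold higher. Among them were Apln (3.01), Csf3 (3.92), and the leukocyte adhesion gene Selp (1.93) and the chemokine-binding Ackr1 (44.7 and 174 CPM). For Csf3, Ackr1 and Selp, 3 cells held 79.2%, 69.0% and 64.6% of the IRI UMIs.

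Matrix genes had a median of 1.70 (percentile 100), with 8 of 10 at least 2-fold higher, among them Plaur, the urokinase receptor (2.71), and Mmp14 (14.2 and 55.4 CPM). Lox (5.76, 3.20 to 11.10) had 1 sham UMI and 74.4% of its IRI UMIs in 3 cells, and Timp1 (3.11) turned to -0.74 without the 3 cells with most UMIs in each library. Mt1 had 6.47 CPM in sham and 1931 CPM in IRI, a log2 ratio of 8.22 (7.34 to 9.28), and Mt2 7.45, with Hmox1 at 1.78 and Osgin1 at 1.64 in the same list, whose median was 0.71 (percentile 100). Glucocorticoid-inducible genes had a median of 1.06 (percentile 99.97), with Errfi1 at 3.11, Map3k6 at 1.60, Fkbp5 at 1.46 and Zbtb16 at 1.39. Interferon-gamma-inducible genes had a median of -1.05 (percentile 0), and 10 of 20 were at least 2-fold lower, among them Cxcl10 (-1.94), the guanylate-binding genes Gbp7 (-1.61) and Gbp4 (-1.58), and Psmb9, an immunoproteasome subunit (-1.48). The Cxcl10 ratio came from 58 and 12 UMIs, in 8 cells of each library, and 3 cells held 69.0% of the sham UMIs.

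The largest endothelial ratios by the rule were those of Sphk1, which makes sphingosine-1-phosphate (7.26, 4.76 to 12.58, from 1 sham UMI), AA467197 (5.44), the iron-siderophore binder Lcn2 (4.94), the scaffold gene Akap12 (4.58) and Cd14 (4.11). At the other end were those of Rgs5 (-6.33, with 94.1% of its sham UMIs in 3 cells), Rbp7 (-4.55), Hcar1 (-4.06), Magix (-3.38) and Tnfsf10, the gene of the death ligand TRAIL (-3.37). For Lcn2, 3 cells held 45.25% of the IRI UMIs, and for Rbp7, 3 cells held 47.5% of the sham UMIs.

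In ILC2-like cells, the receptor genes Pdcd1, Tnfrsf9, Havcr2 and Ctla4 and interferon-stimulated genes were higher after IRI, and heat shock, immediate-early and several chemokine genes were lower. The class had 1100 sham and 1396 IRI cells, and cluster 4 held 1071 of the sham and cluster 5 held 1210 of the IRI cells. T cell activation genes had a median of 0.29 (percentile 99.44), with 6 of 16 at least 2-fold higher. Pdcd1, which encodes the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553, minus strand), had 62.9 CPM in sham and 955 CPM in IRI, a log2 ratio of 3.92 (3.79 to 4.06). The costimulatory receptor gene Tnfrsf9 was at 4.24 (4.03 to 4.46), Havcr2, the gene of TIM-3, at 6.73 (5.17 to 9.01, from 3 sham UMIs) and Ctla4 at 2.17.

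Type I interferon-stimulated genes in ILC2-like cells had a median of 0.85 (percentile 100), with 9 of 24 at least 2-fold higher, among them Ifi44 (3.14, from 2 and 27 UMIs), Oas3 (9.78 and 39.1 CPM), Ifit1 (1.54) and Oas2 (1.52). Unfolded protein response genes had a median of 0.42 (percentile 99.98), with Sdf2l1 at 1.16, Pdia6 at 1.08, Asns at 1.06 (10 and 32 UMIs) and Xbp1 at 1.03. Chemokine ligands had a median of -0.60 (percentile 0.02) with members in both directions: Cxcl3 at 5.56 (2 and 145 UMIs), Cxcl2 at 1.91, Cxcl9 at -2.38 and Ccl1 at -1.91. Immediate-early genes had a median of -0.40 (percentile 0), with Fosb at -0.91, Fos at -0.89, Nr4a1 at -0.89 and Ier3 at 0.96. Heat shock genes had a median of -0.44 (percentile 0.05), with Hspb1 at -2.31, Hsph1 at -0.84, Hspa1b at -0.62 and Hspd1 at -0.62. Among named genes, the largest ratios were those of Havcr2, Edil3 (5.45), Acod1, which makes itaconate (0 sham UMIs, at least 32.1-fold higher), the histamine-forming Hdc (4.56, with UMIs in 70 of the IRI cells and also a gene of mast or basophil-like cells, a source not excluded) and Ncald (4.45). Lowest were those of the lymphotoxin gene Ltb (-2.63), Art2b (-2.54), Wdr86 (-2.38), St6galnac5 (-2.25) and Rap1gap2 (-2.22).

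In ILC3-like cells, the same receptor genes Pdcd1, Havcr2, Tnfrsf9 and Ctla4 were higher after IRI. The class had 1309 sham and 1189 IRI cells. Cluster 2 held 1196 of the sham cells, and clusters 2, 13 and 20 held 451, 474 and 216 of the IRI cells. The clusters were not weighted in this class, so a different mix of cells and a change within cells were not told apart. The median log2 ratio of all genes was 0.14. T cell activation genes had a median of 0.41 (percentile 99.88), with Pdcd1 at 4.97 (4.60 to 5.36), Havcr2 at 3.94, Tnfrsf9 at 2.49 and Ctla4 at 1.95. Chemokine ligands had a median of 0.85 (percentile 100, or 93.5 over members with at least 100 UMIs), with 8 of 17 at least 2-fold higher. The members with the largest ratios had few UMIs and are not read as expression by these cells. In IRI, Cxcl5 and Ccl11 stood at 2.30 and 2.09 CPM in ILC3-like and at 2.40 and 2.13 CPM in B cell-like cells, a level that free RNA from fibroblasts would give. Cxcl5 and Ccl9 had 0 sham UMIs and were at least 8.43-fold and at least 8.04-fold higher (3 cells held 76.2% of the Ccl9 UMIs), Ccl17 was at 2.81 (8 and 49 UMIs), and Ccl11 at 1.71 (7 and 20 UMIs).

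Glucocorticoid-inducible genes in ILC3-like cells had a median of 0.41 (percentile 99.91), with Map3k6 at 1.69, the chemokine receptor gene Cxcr4 at 1.60, Pik3ip1 at 1.41 and Fkbp5 at 0.75. Memory T cell genes had a median of -0.17 (percentile 0.31, or 12.5 with means over cells), with the granule gene Nkg7 at -2.12, the transcription factor gene Tbx21 at -1.09, Ahnak at -0.93 and Id2 at 0.70. The rule for named genes took Ephx2 (6.22, 4.65 to 8.51, from 3 sham UMIs), Acod1 (5.49, 3.90 to 7.78, from 3 sham UMIs), Ptprf (4.49), Palld (4.22) and Gzmf (3.54, with 83.8% of its IRI UMIs in 3 cells). Of the Ephx2 UMIs in IRI, 46.15% lay in 3 cells. In the other direction it took Nmbr (-2.66), Shank2 (-2.12), Cfap54 (-1.80), Mfrp (-1.72) and Spin2c (-1.56).

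In NK or ILC1-like cells, the protease gene Gzma and glucocorticoid-inducible genes were higher after IRI, and Zfp683 was lower. The class had 366 sham and 373 IRI cells. MHC class II genes had a median of 0.81 (percentile 100), with H2-Aa at 1.31, Cd74 at 1.02, H2-Eb1 at 0.93 and H2-Oa at 1.49 (5 and 16 UMIs). B cell markers, with a median of 1.02, moved with them, 3 cells held 50.8% of the IRI UMIs of H2-Aa, and the list median was 0.46 with doublet calls kept, where H2-Oa was at -0.86. Glucocorticoid-inducible genes had a median of 0.33 (percentile 99.84), with Cxcr4 at 1.80, Fkbp5 at 1.42, Pik3ip1 at 0.90 and Tsc22d3 at 0.36. Effector molecules had a median of -0.09, within the range of random lists (percentile 15.3), with Csf2 at 2.35 (52.98% of its IRI UMIs in 3 cells), Gzma at 1.15 (1.06 to 1.24), Il13 at 1.32 (6 and 17 UMIs) and Tnfsf11 at 1.04 (9 and 21 UMIs, and -0.91 under the stricter cell filter). Highest by the rule were the retinoid enzyme gene Dhrs3 (2.63), Gpr55 (2.27), Sft2d2 (2.11), Abcb1b (2.11) and Pde4d (1.90). Lowest were Zfp683 (-3.72), Tesc (-2.74), Mmp9 (-2.51), Il27ra (-1.90) and the phosphatase gene Ptpn6 (-1.84).

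In T-like cells, the activation receptor genes Tnfrsf9 and Pdcd1 were higher after IRI, and memory genes and several effector genes were lower. The class had 1463 sham and 1855 IRI cells, and its clusters took different shares in the libraries. Effector molecules had a median log2 ratio of -0.20 (percentile 0.09), with 2 of 23 at least 2-fold higher and 4 at least 2-fold lower. Gzma (chromosome 13, 113093825 to 113100981, minus strand) had 597 CPM (579 to 616) in sham and 1273 CPM (1251 to 1296) in IRI, a log2 ratio of 1.09 (1.04 to 1.14). With the clusters of the class held at their sham shares, Gzma was at -0.08, while the effector list stayed at -0.20. As Gzma leads 1 of these clusters, a different mix of cells and a higher level within cells were not told apart. The chemokine gene Xcl1 was at -1.17 (-1.27 to -1.07), Nkg7 at -1.16 and Il2 at -3.43 (31 and 4 UMIs). Memory T cell genes had a median of -0.28 (percentile 0), with Tbx21 at -0.84, Ahnak at -0.80, Nkg7 as above and Lgals3 in the other direction at 1.46 (1.30 to 1.63). For memory genes, too, a different mix of cells and a change within cells were not told apart.

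T cell activation genes in T-like cells had a median of 0.16 (percentile 99.36, or 95.01 against random lists not matched on expression). Tnfrsf9 was at 1.93 (1.77 to 2.10), Pdcd1 at 1.84 (1.70 to 1.98), Havcr2 had 6.14 and 12.3 CPM, and Tnfrsf4, the gene of OX40, was at 0.99. Chemokine receptors had a median of -0.26 (percentile 0.13, or 8.30 with means over cells), with the gut-homing receptor gene Ccr9 lower (136 and 68.2 CPM), Ccr8 at 0.86, Cxcr1 at 1.52 (5 and 20 UMIs) and Gpr15 from 9 and 25 UMIs. All but 1 of 11 glucocorticoid-inducible genes were higher, with a median of 0.34 (percentile 99.96), among them Pik3ip1 (0.84), Cxcr4 (0.72), Map3k6 (0.69) and Tsc22d3 (0.47). MHC class II genes had a median of -0.46 (percentile 0), with Ciita at -2.17, H2-Ab1 at -1.04, H2-DMb1 at -0.76 and H2-Aa at -0.72. Markers of B cells (-0.29) and of plasma cells (-0.81) moved with them.

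By the rule, the largest T-like ratios began with the mast cell protease genes Mcpt1 (8.73, 6.25 to 14.04, from 1 sham UMI) and Mcpt2 (0 sham UMIs, at least 114-fold higher), whose IRI UMIs lay entirely in 3 and 2 cells. Then came Rnf180 (4.37), the lipid transporter gene Abcb4 (3.05), Palld (2.93), Frmd5 (2.22), the growth factor gene Tgfb3 (2.09), Ank2 (2.07), Tg (1.98) and Tnfrsf9. The smallest were those of Zfp683 (-3.53, -4.26 to -2.88), Art2b (-2.95), Dnah8 (-1.42), the protease gene Ctsw (-1.36), the vitamin D receptor gene Vdr (-1.35), St3gal6 (-1.35), Hmmr (-1.34), Cap2 (-1.33), Trbv20 (-1.32) and Parp16 (-1.30). Of the sham UMIs, 3 cells held 39.9% for Trbv20, 34.0% for Hmmr and 27.9% for Vdr. UMIs of these genes were found in 47, 25 and 37 sham cells and in 50, 26 and 34 IRI cells.

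Cells gated as CD4 T cells, which bear on the study's question most directly, had lower levels of memory-associated genes, Cd44 and Ifng after IRI. The gate held 423 sham cells, 3.99% (3.63 to 4.38) of all cells and 28.9% (26.6 to 31.3) of T-like cells, and 497 IRI cells, 5.02% (4.60 to 5.47) and 26.8% (24.8 to 28.9). Memory T cell genes had a median of -0.24 (percentile 0), with 6 of 24 higher, Nkg7 at -1.46, Tbx21 at -0.80, S100a6 at -0.67 and the IL-18 receptor gene Il18r1 at -0.54. For S100a6, 3 cells held 47.0% of the sham UMIs, and UMIs were found in 44 sham and 53 IRI cells. Cd44 (chromosome 2, 102811141 to 102901665, minus strand), an adhesion receptor of memory cells, had 199 CPM in sham and 139 CPM in IRI, a log2 ratio of -0.52 (-0.70 to -0.33). Ifng (chromosome 10, 118441046 to 118445892, plus strand), the gene of interferon-gamma, had 270 and 151 CPM, a log2 ratio of -0.84 (-1.01 to -0.67), and Cd4 itself (chromosome 6, 124864692 to 124888221, minus strand), which set the gate, -0.24. The T-like clusters took different shares of the gate in the libraries. With them held at their sham shares, Ifng was at -0.48, Cd44 at -0.48 and the memory list at -0.22. This weighting does not cover a different mix within a cluster. Cluster 6 alone held 47.3% of the sham and 51.3% of the IRI gated cells. A different mix of gated cells therefore stays open for Ifng, Cd44 and the memory list.

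Naive and recirculating lymphocyte genes had a median of 0.06 in the gate, within the range of random lists (percentile 70.9), with Satb1 at 0.87, Dapl1 at -1.92 and Igfbp4 at -0.69. Dapl1 had 57 and 19 UMIs, and 3 cells held 43.9% of those in sham. Effector molecules had a median of -0.10 (percentile 3.25), with Il2 at -4.92 (-10.28 to -2.31, from 24 and 1 UMIs), Nkg7, Csf2 at 1.25 (8 and 24 UMIs, in 7 and 8 cells) and Il13 at -1.24. The Il13 ratio came from 30 and 16 UMIs, in 14 cells of each library, with 53.3% of the sham UMIs in 3 cells. Cytokine receptors of innate-type activation had a median of 0.24 (percentile 99.77, or 6.11 with means over cells), with Il2ra at 0.66, Il23r at 0.61, Il12rb2 at -0.59 and Il12rb1 at -0.57. Plasma cell markers had a median of -2.36 and B cell markers of -0.71 in the gate.

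The share of gated cells with a Cd44 UMI was 39.5% (34.8 to 44.3) in sham and 34.0% (29.8 to 38.4) in IRI, at median depths of 4042 and 4545 UMIs. Thinned to 1000 UMIs, which left out 14 sham and 19 IRI cells, it was 10.8% and 11.3%, and thinned to 2000 UMIs, which left out 46 cells of each library, 23.9% and 18.6%, so no order is read from it. The share with an Ifng UMI was 22.2% (18.3 to 26.5) and 13.9% (10.97 to 17.2), and 13.9% and 9.21% after thinning. For Ccr7, a receptor of naive and recirculating cells, it was higher in IRI, 42.8% (38.0 to 47.7) and 54.7% (50.2 to 59.2), and 26.4% and 32.6% after thinning. For the cytokine gene Il17a it was alike, 8.27% (5.83 to 11.3) and 8.05% (5.81 to 10.8). In fibroblast-like cells, at median depths of 8540 and 12003 UMIs, the background share was 2.32% and 2.03% for Ifng and 6.26% and 3.90% for Ccr7. Fibroblast-like cells express Cd44 themselves and give no background for it.

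In B cell-like cells, MHC class II and interferon-stimulated genes were lower after IRI, and Fkbp5 was higher. The class had 2789 sham and 2302 IRI cells. All 12 MHC class II genes were lower, with a median log2 ratio of -0.52 (percentile 0). Ciita, the transactivator of these genes, had 251 CPM in sham and 121 CPM in IRI, a log2 ratio of -1.06 (-1.15 to -0.96), and H2-DMb2 was at -1.18 (-1.29 to -1.07), H2-DMb1 at -1.04 and H2-Ab1 at -0.82. The B cell-like clusters took different shares in the libraries, and with them held at their sham shares the median was -0.48 and Ciita was at -0.81. Type I interferon-stimulated genes had a median of -0.40 (percentile 0), with Oas3 at -1.83, Usp18 at -1.23, Slfn5 at -1.09 and Ifit3 at -1.05, each from under 200 UMIs. Interferon-gamma-inducible genes had a median of -0.23 (percentile 0.01, and -0.07 with the clusters at their sham shares), with Gbp5 at -0.39 and Irf1 at -0.38 besides Ciita. Glucocorticoid-inducible genes had a median of 0.24 (percentile 99.93), with Fkbp5 at 2.40 (2.23 to 2.58), Zbtb16 at 1.14, Pik3ip1 at 0.79 and Cxcr4 at 0.45.

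By the rule, the largest B cell-like ratios were those of Tbc1d9 (2.24, with 10.4 and 49.1 CPM), Pmepa1, a brake on TGF-beta signalling (1.56), the kinase gene Sgk3 (1.47), Mcmdc2 (1.37), Tmem108 (1.24), Gkap1 (1.23), Zfp69 (1.23), Arap2 (1.23), Cmc2 (1.21) and Mfap1b (1.13). The smallest were those of the histone deacetylase gene Hdac9 (-1.64, -1.98 to -1.31), H2-T24 (-1.52), the calcium channel gene Cacna1i (-1.39), Ptx4 (-1.27), Ano8 (-1.19), the B cell transcription factor gene Pou2f2 (-1.18), H2-DMb2, Nudt5 (-1.18), Thumpd2 (-1.16) and Ikzf3, the gene of Aiolos (-1.15).

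In plasma cell-like cells, cell cycle genes were higher after IRI and light chain usage differed. The class had 1991 sham and 1205 IRI cells, and the median log2 ratio of all genes was 0.20. Cell cycle genes had a median of 1.48 (percentile 100), and 21 of 22 were at least 2-fold higher, among them Aurkb (2.35, 2.03 to 2.68), the cyclin gene Ccna2 (1.95), Plk1 (1.93) and Tpx2 (1.79). Aurkb UMIs were found in 58 sham and 98 IRI cells. With the clusters of the class held at their sham shares the median was 0.40, and Aurkb was at 1.15. A cluster led by cell cycle genes is among them, so the value does not tell more cycling cells from higher levels within cells. Glucocorticoid-inducible genes had a median of 0.57 (percentile 99.68), with Fkbp5 at 2.08 (1.98 to 2.18), Ddit4 at 1.47, Zbtb16 at 1.43 and Map3k6 at 1.39. Type I interferon-stimulated genes had a median of 0.48 (percentile 99.79, or 93.8 over members with at least 100 UMIs), with Rtp4 at 3.49 (6 and 41 UMIs), Oas1a at 1.62 (8 and 15 UMIs), Oas3 at 1.19 and Usp18 at 0.83.

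By the rule, the largest plasma cell-like ratios were those of the antibody genes Ighg2c (4.28), Igkv1-88 (3.32), Igkv4-72 (2.92), Igkv7-33 (2.90), Igkv12-38 (2.88) and Igkv4-90 (2.64), and of Sbno2 (2.96), the interferon-inducible Gbp2 (2.73), the kinesin gene Kif22 (2.52) and the p53 target Sesn1 (9.43 and 53.4 CPM). In IRI, 3 cells held 98.1% of the Ighg2c, 99.97% of the Igkv12-38, 81.7% of the Igkv7-33 and 58.7% of the Igkv4-90 UMIs, and without the 3 cells with most UMIs in each library Ighg2c was at -0.43 and Igkv12-38 at -8.18. The smallest were those of Igkv5-45 (-5.47), Igkv6-25 (-2.77), Igkv2-137 (-2.76), Igkv8-30 (-2.70), Igkv13-84 (-2.35) and Iglc3 (-2.05), and of the growth factor gene Nrg2 (-2.04), Tmem266 (-1.85), the tubulin acetyltransferase gene Atat1 (-1.77) and Eef1akmt3 (-1.62).

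In epithelial-like cells, antimicrobial Reg3 genes and glucocorticoid-inducible genes were higher after IRI. The class had 391 sham and 301 IRI cells, whose clusters expressed gland and gastric-type genes such as Muc6 and Pgc, so it does not stand for the absorptive epithelium of the small intestine. Antimicrobial and acute-phase genes had a median of 1.53 (percentile 100), with 8 of 13 at least 2-fold higher. Reg3b (chromosome 6, 78370657 to 78373466, plus strand), a secreted antibacterial lectin, had 420 CPM in sham and 3924 CPM in IRI, a log2 ratio of 3.22 (3.18 to 3.27), and Reg3g, whose sequence is close to it, 2.98, with 48.25% of its IRI UMIs in 3 cells. Lcn2 was at 3.06 with 81.8% of its IRI UMIs in 3 cells, and Retnlb, with 0 sham UMIs, was at least 36.2-fold higher with all its UMIs in 4 cells. Absorption and digestion genes had a median of 0.64 (percentile 100), with the maltase gene Mgam at 1.52, Slc2a5 at 1.16 (9 and 18 UMIs), Mogat2 at -1.13 (27 and 11 UMIs) and Fabp1, with 0 sham UMIs and 26 IRI UMIs in 3 cells, at least 9.70-fold higher.

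Glucocorticoid-inducible genes in epithelial-like cells had a median of 0.58 (percentile 100), with Zbtb16 at 2.06 (1.79 to 2.33), Map3k6 at 1.60, Fkbp5 at 1.52 and Pik3ip1 at 0.78. The rule took as highest Cps1 (0 sham UMIs, at least 163-fold higher), Clca4b (0 sham UMIs, at least 45.5-fold higher), the mucin gene Muc3 (4.01), Reg3b and Reg3g. For Cps1 and Muc3, 3 cells held 98.2% and 95.8% of the IRI UMIs, and Clca4b UMIs lay in 4 cells. In the other direction it took Sectm1b (-2.58), Gast, the gastrin gene (-2.26, but 0.25 without the 3 cells with most UMIs in each library), Rflna (-1.63) and Epha7 (-1.62).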

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

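The tests on glucocorticoid-inducible genes and on Pdcd1 given in this closing section were chosen only after those results were seen. Several gene lists stood at opposite ends of the random lists in different cell classes, which is what singled them out, and the difference between classes was not tested for any of them. Type I interferon-stimulated genes had a median log2 ratio of 1.61 in fibroblast-like and -0.40 in B cell-like cells. Interferon-gamma-inducible genes had medians of 0.26 in ILC3-like and -1.05 in blood endothelial-like cells. MHC class II genes had medians of 0.81 in NK or ILC1-like and -1.49 in fibroblast-like cells, in both of which B cell markers moved the same way. Unfolded protein response genes had medians of 0.42 in ILC2-like and -0.0625 in B cell-like cells. Cell cycle genes had medians of 1.48 in plasma cell-like and -0.18 in T-like cells, and the plasma cell-like value was 0.40 with the clusters at their sham shares.

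Memory T cell genes had medians of 0.49 in plasma cell-like and -0.44 in ILC2-like cells, and naive and recirculating lymphocyte genes 0.47 in ILC3-like and -0.69 in fibroblast-like cells. These lists were made for T cells, and their members in other classes are not read as T cell states. A class too small to compare, mast or basophil-like cells, numbered 28 in the IRI library and 5 in the sham library.

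The ILC2-like cells of the libraries lay apart, with a separation index of 0.819, which is why different clusters held them. Leaving out immediate-early, heat shock and NF-kB feedback genes kept 1.008 of that index. Thinning cells to 2000 UMIs without immunoglobulin genes and markers of other classes kept 0.8428. So neither the genes of those lists, nor depth together with the genes left out, account for most of it. Other genes that respond to dissociation stayed in, as did free RNA of genes such as Mt1, Mt2 and Cxcl5. Neither explanation was therefore excluded as a whole. A technical shift of all cells of a library stays open: B cell-like cells, which shared the handling, had an index of 0.462, which is 0.5645 of the ILC2 index and above the limit of 0.5 set in advance. The indices of T-like (0.408) and epithelial-like cells (0.2504) lay below 0.5 of the ILC2 index, T-like cells only just, and that of fibroblast-like cells (0.779) near the ILC2 index, so the shift was not alike in all classes. A response of ILC2 to the injury may also contribute, but with 1 library per group it was not tested apart from such a shift.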

How the results depend on the processing

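The alternatives without clusters of low UMI count, without the 3 cells with most UMIs of a gene in each library, and with the clusters of a class at their sham shares were chosen after seeing the data. No paired analysis was possible because each group has 1 library, so the results come from no test. Of the ratios of class shares under other filters, doublet rules, resolutions and denominators, 78 stayed within the interval of the main value and 3 did not. The B cell-like ratio, 0.884, was 0.501 under the strict cell filter and 0.741 at Leiden resolution 2, where B-like clusters of 1647 sham and 1760 IRI cells and of 734 and 870 cells stayed unnamed. The plasma cell-like ratio, 0.648, was 0.594 with each library clustered alone, and the cause was not tested. Of the list medians, 434 stayed within their interval and 13 moved beyond it. A change of sign was counted only where the main interval held a single sign, and 2 such medians changed sign. These 2 were the immediate-early genes of the whole library, 0.20 in the main setting and -0.14 with TMM or median-of-ratios factors, which remove the shift of all genes. The NK or ILC1-like MHC class II median, 0.81, was 0.37 with means over cells, 0.46 with doublet calls kept and 0.35 under the strict filter, and the cause was not tested. Of the single-gene ratios, 2063 stayed within their counting interval, 545 moved beyond it and 8 of at least 2-fold in the main setting changed sign. Sign changes of smaller ratios were counted among the others. With the clusters of a class at their sham shares, Gzma in T-like cells was at -0.0805 and the plasma cell-like cell cycle median, 1.48, was 0.40. Clusters led by these genes took larger shares in IRI, and the weighting does not tell cell mix from change within cells. Ifng in the CD4 gate, -0.84, was at -0.48 with that weighting. Without the 3 cells with most UMIs, Gast in epithelial-like cells was at 0.25, Ighg2c and Igkv12-38 in plasma cell-like cells at -0.43 and -8.18, and Timp1 in endothelial-like cells at -0.74, because few cells held those UMIs. Timp1 was at -1.22 at Leiden resolution 2, H2-Oa in NK or ILC1-like cells at -0.86 with doublet calls kept and Tnfsf11 there at -0.91 under the strict filter, each from few UMIs or cells. In the CD4 gate, Ifng was at -1.18 with means over cells, and the ratio of the shares with a Cd44 UMI was 1.05 after thinning to 1000 and 0.780 after thinning to 2000 UMIs, against 0.861; the cause was not tested. Of the 120 genes named in the main classes, the rule took 59 again with a minimum of 30 UMIs and 50 without the condition on the highest class, since the first admits genes of lower count and the second genes higher in another class. Of the source shares, 43 stayed within their interval and 15 moved, all with doublet calls kept. The planned use of clusters named CD4 T-like gave no value, since no cluster took that name. Depth limits genes with few UMIs, and the number of libraries limits every comparison.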

Other observations

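The tests on glucocorticoid-inducible genes and on Pdcd1 in this part were chosen only after the results were seen. Dendritic cells were not among the main comparisons. In conventional dendritic cell-like cells (228 sham and 192 IRI), type I interferon-stimulated genes had a median log2 ratio of 1.04 (percentile 100, with 13 of 23 at least 2-fold higher), and chemokine ligands a median of -0.67 (percentile 0). Ccl22, which attracts CCR4-bearing T cells and is one of the markers used to name the class, had 184 CPM in sham and 24.6 CPM in IRI. Cluster 15, of low UMI count, held 203 of the sham and 123 of the IRI cells, and cluster 30 held 25 and 69. A different mix of cells therefore stays open for these values. The class name is uncertain, as monocyte or macrophage markers had the second naming score in both clusters. That score was 4.30 against 4.80 in cluster 15, where Lyz2 and Il1b were among the top genes, and 3.32 against 4.43 in cluster 30. In plasmacytoid dendritic cell-like cells (90 and 96), innate cytokines had a median of 1.41 over 5 measured members and glucocorticoid-inducible genes 0.64 (percentile 99.97).

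Mast or basophil-like cells, 28 of the IRI cells, held 25.3% of the IRI Gzmb UMIs and 16.7% of the IRI Ccl3 UMIs. In the sham library, 5 such cells held 4.46% and 5.26%.

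Glucocorticoid-inducible genes had a positive median in each of the 9 main classes, from 0.18 in ILC2-like cells, within the range of random lists (percentile 94.6), to 1.06 in blood endothelial-like cells. Free RNA from 1 source as the whole cause would add a like number of list UMIs to every cell, but at the depth of the IRI cells the difference ran from -0.7205 UMIs per cell in ILC2-like to 20.5 in blood endothelial-like cells. This number sums the list, so abundant members weigh most, such as Cxcr4 with 2660 of 5469 CPM in IRI B cell-like cells. A fall of such a member within a class can hide added RNA, so a part from free RNA was not excluded. Scaling would move matched random lists as much, but the list median exceeded theirs by at least 0.1911 in each main class. A hypothesis left open is that a systemic steroid response differed between the pools, which could come from the injury or from the time of collection, and neither was tested.

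Pdcd1 was higher in ILC3-like cells of the IRI library, at 171 CPM against 5.45 CPM in sham. Free RNA from ILC2-like cells, which had 955 CPM, would reach other classes too, but the higher of the IRI levels in fibroblast-like and B cell-like cells was 0.042 of that in ILC3-like cells. Other lymphoid and myeloid classes were higher as well, NK or ILC1-like cells with 3.97 CPM in sham and 98.2 CPM in IRI and conventional dendritic cell-like cells with 0 and 53.2 CPM, so the difference was not particular to ILC3-like cells. ILC2-like cells counted among ILC3-like cells would have to make up 17.9%, and the ILC2 markers reached 0.1708 of the CPM that this share would bring. Higher Pdcd1 in ILC3-like cells themselves may therefore be a hypothesis to follow up, found and tested on the same data, and a library-wide shift was not tested for it.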
